A study of Mus musculus with 16 samples.

How the data were processed

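Gene expression was measured by bulk RNA sequencing of total RNA from mouse ventricles, in 4 male control, 4 male CKD, 4 female control and 4 female CKD samples. Per the labels' protocols, RNA was isolated with a Qiagen RNeasy Plus Mini kit and sequenced as 50 bp paired-end reads on an Illumina HiSeq2500. The group of each sample was taken from its treatment and sex labels, and replicate numbers within a group follow the order of the records and only name a sample. The number after the letter C in the sample titles is 6 in 10 samples (5 of them CKD), 2 in 3 (1 CKD), 3 in 2 (1 CKD) and 5 in 1 (1 CKD). What it stands for is not given in the sources used here, nor is the meaning of the number that ends each library name, and both were used as possible technical groupings.

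The authors deposited raw read counts per gene for all samples in 1 table, as whole numbers with no normalization. Per the submitters' processing notes the tools were FastQC, MultiQC, STAR 2.6.1d, featureCounts from Subread 1.6.3 and DESeq2 1.30.1, with mm10 as the genome. The annotation release, the strand setting and the treatment of reads that fit several places are not given in the sources used here. A gene that shares sequence with a pseudogene can therefore gain or lose counts, and genes on opposite strands cannot be told apart with certainty. The table held 33399 Ensembl gene identifiers; 33367 were matched to GENCODE release M21 (GRCm38, the assembly that mm10 names), 32027 of them with the same version number, and coordinates, gene types, exon lengths and GC content came from that release.

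Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the 4 groups (minimum count 10, minimum total 15), which left 16400 genes with at least 99.8% of the counts of every library. Library sizes were scaled by TMM. Totals of about 10203700 to 13626000 counts per library give little counting error for genes well above the filter, so the spread between mice sets the precision: the common biological coefficient of variation was 0.225, and the median standard error of the log2 fold change was 0.149 for 8 against 8 mice and 0.213 for 4 against 4 females.

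CKD was compared with control by edgeR's quasi-likelihood F test with sex as a covariate. CKD effects in each sex, their difference (the interaction), and sex differences in control and in CKD mice were contrasts of a model with the 4 groups as levels, so all 16 libraries share the estimate of spread. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05, and tests are two-sided. Xist and 4 Y-linked genes were left out of the counts of sex differences. CPM values are given as mean ± SD over mice, and log2 fold changes come from the fitted model.

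The tests, the gene lists and the naming rule were fixed before the data were examined. The lists, 45 in all, cover cardiac electrophysiology and contraction, metabolism, stress and hormone responses, immunity, and markers of the cell types a ventricle sample can hold; 43 had at least 5 tested members, and the other two, for skeletal muscle and lung, were left out. Lists were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the 43 lists. Fry, camera with the correlation estimated from the residuals, and exact permutation of list means within sex were run beside it; the permutation was chosen after seeing the data. A list counts as called only for a shift in a common direction, so fry's test for change in either direction does not enter the calls.

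The genes named were a fixed panel of 18 genes of conduction, calcium handling, hypertrophy and fibrosis, whatever their result. For CKD against control they also were up to 8 genes in each direction with the largest fold change among those past the threshold, with a mean of at least 1 log2 CPM and the same sign in both sexes, leaving out predicted genes, clone names and pseudogenes; 4 higher and 5 lower genes met this. From each called list up to 4 members past the threshold were named, or 2 with the lowest p where none was past it, and from other lists up to 2 members past it. For each other comparison up to 6 genes past the threshold were named. Genes outside this rule are named as chosen after their values were seen. Values of 2 genes that met the rule are not reported here, though all counts include them.

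Alternatives were DESeq2 1.42.0, limma-voom with sample quality weights, RLE and upper-quartile scaling, leaving out mitochondrially encoded genes, no filter and a stricter filter (1 CPM in 8 libraries), the title code number as a factor, only the libraries with title code number 6, 1 surrogate variable from sva 3.50.0, no sex term, a test against a 1.2-fold change, only the 8 libraries compared, and each library left out in turn. Removal of GC and length trends per library (lowess, span 0.3), library numbers 3 to 6 as a factor, and leaving out male_CKD 4 and female_control 2 were chosen after seeing the data. Each comparison was also repeated over other splits of the same samples, up to 100 of them. The sample labels give no replicate numbers, so no pairs of mice were formed.

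The procedures were tested on simulated counts with the real means and library sizes, drawn independently for each gene. The simulated counts held no sex difference, no GC trend and no outlying library. The real libraries hold such structure, so the rates below need not carry over to them. For CKD against control (16223 genes) the test recovered 25.4% of 67 genes changed 1.5-fold, 74.2% of 66 changed 2-fold and 100% of 65 changed 3-fold, with 8 false among 139 calls. For females alone (16245 genes) it recovered 15.4% of 65, 61.2% of 67 and 78.1% of 64, with 4 false among 105 calls. In a simulation of 16247 genes that vary independently, which real genes do not, camera called the changed list and 0 of 40 lists with no changed gene, both with the preset correlation and with an estimated one. Overlaps between genes were computed from exon positions with Python 3.11.15, and plots were drawn with matplotlib 3.10.9.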

Results

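Bulk RNA sequencing was performed on the ventricles of 16 C57BL/6 mice, 8 controls and 8 with chronic kidney disease (CKD), with 4 males and 4 females in each arm. From 8 weeks of age the CKD mice received chow with 0.25% adenine in alternation with plain chow for 6 weeks, and controls received plain chow. Adenine is oxidised to a product that crystallises in kidney tubules and damages them. The regimen aimed at a blood urea nitrogen, a blood measure of kidney filtration, of 40 to 70 mg/dL; values of single mice were not used here. The title of the series names pro-arrhythmic remodelling, and the comparisons below ask which ventricular transcripts differed with CKD, in both sexes together and in each sex.

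Read counts per gene were available for 33399 genes, of which 16400 had enough counts to be tested. The libraries held between about 10203700 and 13626000 counts. Mitochondrially encoded transcripts took 9.28% ± 0.594 (SD, n = 8) of the counts in controls and 9.29% ± 0.605 (SD, n = 8) in CKD mice. Xist, the transcript that coats the inactive X chromosome, had 4401 to 8957 counts in the female libraries and 11 to 38 in the male ones. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together had 1737 to 4514 counts in the male libraries and 5 to 12 in the female ones, so every library matched its sex label. Between libraries of one group the counts differed by 8.03 to 58.8 chi-square units per degree of freedom, so none was a second copy of another.

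Library male_CKD 4 stood apart from the others. It had 1411 genes outside the range of the other 15 libraries by more than 0.5 log2 units, and female_control 2 had 858. On the second principal component male_CKD 4 lay at -80.0 and the other 3 male CKD libraries between 0.422 and 11.7. The first component took 39.7% of the variance of log2 CPM (read counts scaled to the size of the library), and across genes its loadings correlated with the GC content of the transcripts (Spearman -0.546; genes are not independent replicates). The GC correlation of single libraries ran from -0.492 to 0.0122 in female CKD mice and from -0.471 to 0.145 in female controls. In males it ran from 0.0360 to 0.406 with CKD and from 0.00959 to 0.548 in controls.

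**Figure D1:**
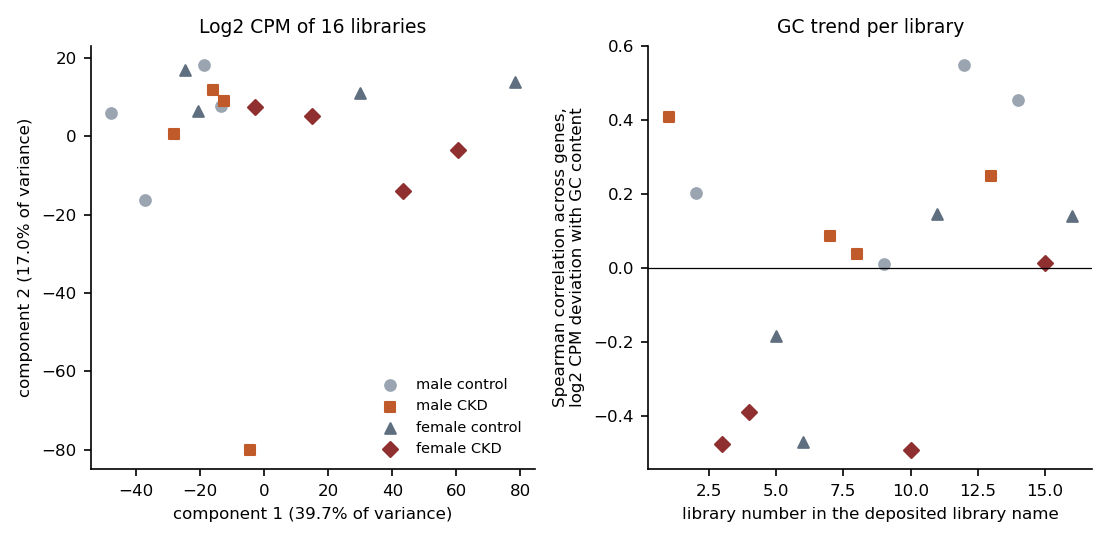
Left, the 16 libraries on the first 2 principal components of log2 CPM, with 39.7% and 17% of the variance; male_CKD 4 lies at -80.0 on component 2. Right, the Spearman correlation across genes between each library's log2 CPM deviation and transcript GC content, against the number in the deposited library name; female libraries numbered 3 to 6 lie between -0.476 and -0.185, and the lowest of all, -0.492, is female_CKD 3, numbered 10.

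CKD ventricles held more transcript of 7 genes and less of 7 others than control ventricles (n = 8 against 8). Rbm3, which encodes a cold-inducible RNA-binding protein, rose from 80.7 ± 10.1 to 152 ± 26.1 CPM (mean ± SD), a log2 fold change of 0.91 (SE 0.11, adjusted p = 0.00192), and 8 of 8 CKD mice lay above every control. Nqo1, a quinone reductase of the antioxidant response, rose from 75.7 ± 9.82 to 116 ± 16.4 CPM (log2 fold change 0.61, SE 0.10, adjusted p = 0.0270). Nt5e, the ectonucleotidase CD73 that forms adenosine from AMP, rose by 0.73 log2 units (SE 0.13) and Mr1, which presents vitamin B metabolites to T cells, by 0.55 (SE 0.10), both with adjusted p = 0.0420. The other 3 higher features were the processed pseudogenes Rbm3-ps, Gm10156 and Gm48583, named after their values were seen, with log2 fold changes of 1.04, 0.98 and 0.96. Of their 25-base words, 88.4%, 80.8% and 100% also occur in Rbm3 transcripts, so their counts cannot be separated with certainty from those of Rbm3.

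Among the lower genes, Rflnb, whose product refilin B binds filamin, fell from 49.5 ± 8.17 to 27.7 ± 5.39 CPM (log2 fold change -0.85, SE 0.11, adjusted p = 0.00298), and Rinl, a Ras and Rab interactor-like gene, from 3.18 ± 0.760 to 1.31 ± 0.294 CPM (log2 fold change -1.26, SE 0.18, adjusted p = 0.00780). Apln, which encodes the peptide ligand apelin, fell from 12.8 ± 5.04 to 4.79 ± 1.4 CPM (log2 fold change -1.41, SE 0.26, adjusted p = 0.0420). P4ha1, a catalytic subunit of the prolyl hydroxylase that modifies collagen, fell by 0.71 log2 units (SE 0.13, adjusted p = 0.0420). Dcakd, named for a dephospho-CoA kinase domain, fell by 0.88 (SE 0.16, adjusted p = 0.0493). The remaining pair, named after their values were seen, were the non-coding transcript 6430562O15Rik (log2 fold change -1.12) and Lrrc55, an auxiliary subunit of large-conductance potassium channels (log2 fold change -2.15, 1.5 ± 0.650 to 0.347 ± 0.273 CPM). In both sexes each of the 14 genes had a fold change of the sign seen over all mice; for Rbm3 it was 0.71 (SE 0.14) in males and 1.11 (SE 0.14) in females, and for Rflnb -0.78 (SE 0.16) and -0.92 (SE 0.16).

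On GRCm38, the assembly named mm10 in the processing notes, Rbm3 (ENSMUSG00000031167.16) spans chromosome X from 8138975 to 8145880 on the minus strand. Nqo1 (ENSMUSG00000003849.8) spans chromosome 8 from 107388225 to 107403206, Nt5e (ENSMUSG00000032420.8) chromosome 9 from 88327197 to 88372092, and Mr1 (ENSMUSG00000026471.14) chromosome 1 from 155127277 to 155146814. Rflnb (ENSMUSG00000020846.6) lies on chromosome 11 from 76019194 to 76027782, Rinl (ENSMUSG00000051735.7) on chromosome 7 from 28788969 to 28798963, and P4ha1 (ENSMUSG00000019916.14) on chromosome 10 from 59323296 to 59373304. Apln (ENSMUSG00000037010.7) lies on chromosome X from 48025146 to 48034853 and Dcakd (ENSMUSG00000020935.8) on chromosome 11 from 102994047 to 103028333. These 9 genes are annotated as protein coding, and the counts cover all exons of a gene together. Exons of genes on the other strand overlap 2.0% of the exon bases of Rbm3, 5.63% of those of Dcakd, 8.47% of those of 6430562O15Rik and 7.35% of those of Lrrc55; whether strand was used in counting is not given in the sources used here.

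**Figure D2:**
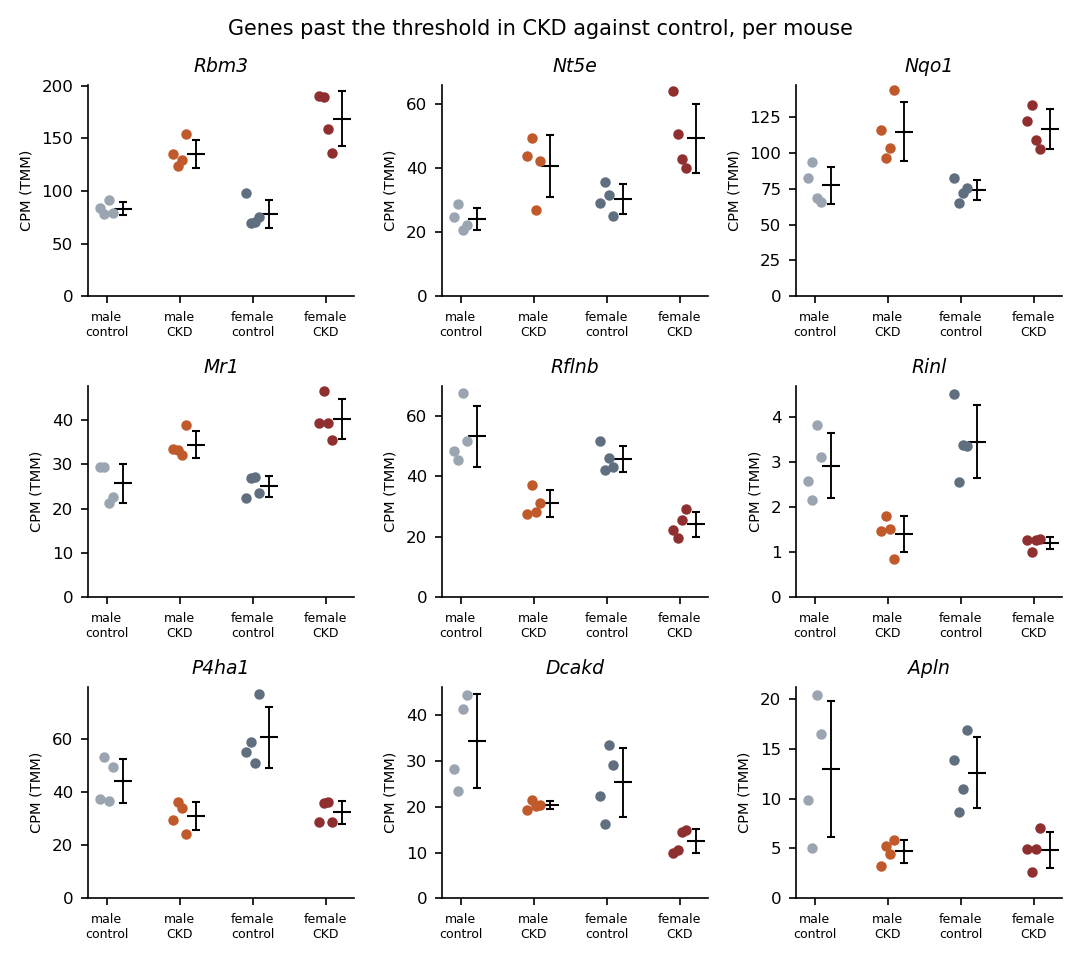
CPM per mouse (points) with mean and SD (bars, n = 4 per group) for the 9 protein-coding genes past the threshold that were named by rule, with CPM scaled by TMM on each vertical axis. Rbm3 lies above every control in 8 of 8 CKD mice.

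The 14 genes passed edgeR's quasi-likelihood F test with sex as a covariate, at a Benjamini-Hochberg adjusted p under 0.05. At an unadjusted p under 0.05 there were 2519 genes, against 820 by chance. DESeq2 called 224 genes higher and 174 lower, limma-voom 121 and 78, and edgeR with the number in the title code as a factor 150 and 84, each set including all 14 genes. Among the 10 libraries with title code number 6, a possible cohort mark, 3 genes were higher and 5 lower, and Rbm3 and Rflnb were the 2 shared with the 14. Dcakd lost its call with RLE scaling and with the stricter filter, which also removed Lrrc55, and Mr1 and Nt5e lost theirs with upper-quartile scaling and without mitochondrial genes. With no sex term Lrrc55, Nt5e, P4ha1 and Dcakd were lost. Against a minimum fold change Rbm3, Rbm3-ps, Gm10156, Rflnb and Rinl were the 5 kept, and with male_CKD 4 and female_control 2 both left out Mr1, Lrrc55, P4ha1 and 6430562O15Rik were lost. With any 1 library left out, Rbm3, its 3 pseudogenes, Rflnb and Rinl kept their calls in all 16 runs, while Nqo1 kept it in 8, P4ha1 in 6, and Nt5e, Mr1, Apln and Dcakd in 4 each. Without any 1 of female_CKD 1, 2 or 3, female_control 3, male_CKD 1 or male_control 4, the calls were 4 higher and 2 lower; without female_CKD 4 they were 17 and 26, and without male_control 2 they were 16 and 21. Without male_control 3 they were 4 and 4, without female_control 4 they were 5 and 3, without male_CKD 4 they were 6 and 4, without male_CKD 3 they were 9 and 4, and without female_control 1 they were 5 and 4.

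None of the panel genes of conduction, repolarisation, calcium handling and hypertrophy passed the adjusted threshold. The transient outward current genes Kcnd2 and Kcnip2 had log2 fold changes of -0.16 (SE 0.13) and -0.15 (SE 0.17). Kcnj2, of the inward rectifier current, had 0.11 (SE 0.13), Cacna1c, the L-type calcium channel, -0.08 (SE 0.15), and Gja1, the gap junction protein connexin 43, 0.20 (SE 0.11). The ryanodine receptor gene Ryr2 had -0.14 (SE 0.10), the calcium pump Atp2a2 0.02 (SE 0.14) and its inhibitor Pln 0.17 (SE 0.08, adjusted p = 0.329). The natriuretic peptide gene Nppb had 0.50 (SE 0.28, adjusted p = 0.404), Nppa 0.02 (SE 0.24), the slow myosin Myh7 0.32 (SE 0.15, adjusted p = 0.328) and the collagen gene Col1a1 -1.24 (SE 0.48, adjusted p = 0.229).

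Of the 18 genes of this panel, 0 passed the threshold in edgeR, 1 had an unadjusted p under 0.05 (Col1a1), and 0 passed in DESeq2 and 0 in limma-voom. The 95% interval of the log2 fold change ran from -0.43 to 0.11 for Kcnd2, from -0.36 to 0.08 for Ryr2 and from -0.04 to 0.44 for Gja1. Nppb in female_CKD 2 and Myh7 in male_CKD 1 lay far above the other 3 mice of their groups, at 343 and 2944 CPM. Of whole lists, the sodium channels (8 members tested, median log2 fold change -0.26, camera adjusted p = 0.399), potassium channels (24, -0.05, 0.687), calcium handling genes (25, -0.04, 0.907), intercalated disc genes (18, 0.04, 0.355), pacemaker and conduction genes (13, -0.13, 0.559) and fetal and hypertrophy genes (11, 0.09, 0.567) were not called. The sodium channel mean still lay below that of the control mice of the same sex in 8 of 8 CKD mice. Of the 8 members 3 had an unadjusted p under 0.05, and exact permutation of the mean gave an adjusted p of 0.260.

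**Figure D3:**
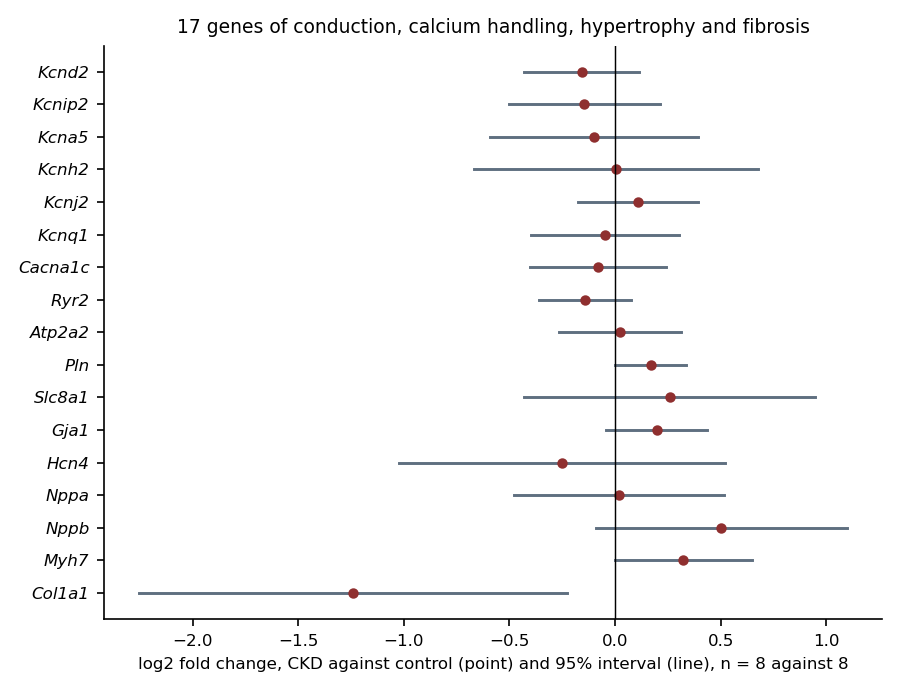
Log2 fold change of CKD against control (point) with its 95% interval (line) for 17 of the 18 genes of conduction, calcium handling, hypertrophy and fibrosis, n = 8 against 8. The interval of Col1a1 runs from -2.25 to -0.23, and its adjusted p is 0.229.

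Antiviral and antigen presentation genes had lower values in CKD ventricles, though as groups they were called only by camera with the preset correlation. All 17 measured members of the interferon response list had negative fold changes (median log2 -0.47), and 11 fell when adjusted over the list alone; Oas1a, a sensor of double-stranded RNA, had -0.72 (SE 0.16) and Xaf1 -0.54 (SE 0.13). Camera with a preset correlation gave the list an adjusted p of 2.06e-11, with adjusted p = 0.293 with an estimated correlation. All 13 antigen presentation genes were negative (median -0.72) and 13 fell when adjusted over the list alone, among them H2-DMa (-1.04, SE 0.21) and H2-DMb1 (-0.83, SE 0.24), which load peptides on MHC class II. Adjusted over all genes, 0 members of this or any other called list passed in edgeR. The antigen presentation list had a camera adjusted p of 6.42e-11, and adjusted p = 0.293 with an estimated correlation. Over the alternative settings its median ran from -0.73 to -0.35 and the value of H2-DMb1 from -0.85 to -0.38. The 7 measured lymphocyte markers, of 14 listed, were negative too (median -0.53, camera adjusted p = 0.00119, adjusted p = 0.293 with an estimated correlation). Of them 3 were past the threshold when adjusted over the list alone. The B cell genes Ms4a1 and Cd79a had -0.88 (SE 0.33) and -0.76 (SE 0.30). Both lay near the floor, at 0.37 to 2.16 CPM and 0.095 to 1.73 CPM over the 16 libraries. The mean of each of these 3 lists lay below the mean of the control mice of the same sex in 8 of 8 CKD mice. That was not particular to them: the sterol, heat shock and sodium channel means also lay below in 8 of 8, and the ribosomal, NRF2 and neutrophil means above. Male_CKD 4 had the lowest antigen presentation mean of the 16 libraries, 3.13 log2 CPM. With male_CKD 4 and female_control 2 both left out the lymphocyte list was not called.

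Most matrix and stromal genes had negative fold changes, though as groups they were called only by camera with the preset correlation. Of 33 extracellular matrix and fibrosis genes, 30 had negative fold changes (median -0.58), and 13 fell when adjusted over the list alone, such as Sparc, a collagen-binding matrix protein (-0.81, SE 0.18), and Cilp, a matrix protein of fibroblasts (-0.97, SE 0.22). The list had a camera adjusted p of 2.50e-11, and adjusted p = 0.450 with an estimated correlation. All 11 fibroblast markers were negative (median -0.32, camera adjusted p = 0.00197, adjusted p = 0.569 with an estimated correlation), with the collagen-processing gene Pcolce at -0.39 (SE 0.13) and Mfap5 at -0.44 (SE 0.21). Of 15 endothelial markers 12 were negative (median -0.21, camera adjusted p = 0.00356, adjusted p = 0.569 with an estimated correlation), and 2 fell when adjusted over the list alone, the VEGF receptor Kdr (-0.72, SE 0.18) and the tight junction gene Cldn5 (-0.78, SE 0.20). All 10 pericyte and smooth muscle markers were negative (median -0.26, camera adjusted p = 0.0248, adjusted p = 0.519 with an estimated correlation), 2 of them past the threshold when adjusted over the list alone, with Higd1b at -0.57 (SE 0.19) and Vtn at -0.55 (SE 0.19).

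In male_CKD 4 the fibroblast marker mean was 4.40 log2 CPM, against 5.98 to 6.16 in the other 3 male CKD mice, and the matrix mean was 3.34, against 4.27 to 4.80. Without this library the matrix list was still called (median -0.49), and the fibroblast, endothelial and pericyte lists were not. The pericyte call was also lost without male_control 3, male_CKD 1, female_control 1 or female_CKD 3, where its median ranged from -0.34 to -0.19 over all left-out runs. It was lost as well among the libraries with title code number 6 and with GC trends removed.

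Genes of translation, respiration and contraction mostly had small positive fold changes. Their lists were called only with the preset correlation of 0.01. The estimated correlations were 0.91 for ribosomal, 0.83 for oxidative phosphorylation and 0.55 for sarcomere genes. Exact permutation of these list means within sex gave p = 0.0167, 0.226 and 0.202, not adjusted over the lists. All 25 ribosomal protein genes had positive fold changes (median 0.25), and 12 rose when adjusted over the list alone, with Rpl3 at 0.34 (SE 0.10) and Rps19 at 0.35 (SE 0.10); the camera adjusted p was 6.42e-11, and adjusted p = 0.497 with an estimated correlation. Of 33 nuclear genes of oxidative phosphorylation, 30 were positive (median 0.17, camera adjusted p = 0.000243, adjusted p = 0.645 with an estimated correlation), with the heart isoform of a cytochrome oxidase subunit, Cox6a2, at 0.29 (SE 0.11). Of 17 adult sarcomere genes 14 were positive (median 0.17, camera adjusted p = 0.0103, adjusted p = 0.642 with an estimated correlation), and 2 rose when adjusted over the list alone, the Z-disc gene Myoz2 (0.35, SE 0.10) and cardiac troponin T, Tnnt2 (0.36, SE 0.10). Male_CKD 4 was the highest library in all 3 lists, with means of 8.65, 10.26 and 11.83 log2 CPM. Without it the ribosomal list was still called and the oxidative phosphorylation and sarcomere lists were not, with medians of 0.0615 and 0.0743; the sarcomere call was also lost without male_control 2 (median 0.11).

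Hormone and stress response lists went in both directions, called only with the preset correlation. Of 16 glucocorticoid targets 15 were positive (median 0.35, camera adjusted p = 0.00197, adjusted p = 0.497 with an estimated correlation), with Arrdc2 at 1.08 (SE 0.35) and the metallothionein Mt1 at 0.37 (SE 0.12). Of 15 atrophy and FoxO targets 11 were positive (median 0.14, camera adjusted p = 0.0248, adjusted p = 0.497 with an estimated correlation), and the translation repressor Eif4ebp1 (0.53, SE 0.11) was the 1 that rose when adjusted over the list alone. This call was lost without male_control 3, male_CKD 1, female_control 1, female_control 2 or female_CKD 4, with medians from 0.05 to 0.20 over all left-out runs. All 11 heat shock genes were negative (median -0.20, camera adjusted p = 0.00663, adjusted p = 0.519 with an estimated correlation), and the chaperone Hsph1 fell when adjusted over the list alone (-0.93, SE 0.18). Among the libraries with title code number 6 the glucocorticoid and atrophy lists were not called. Hsph1 was at 129 CPM in female_control 4 and at 49.6 to 63.2 in the other 3 female controls, and without that library the heat shock list was not called (median -0.0867); its median was -0.31 without male_control 1 and -0.12 without female_CKD 1. Of 20 sterol and lipid synthesis genes 16 were negative (median -0.21, camera adjusted p = 0.00299, adjusted p = 0.293 with an estimated correlation), with 1 past the threshold when adjusted over the list alone and the desaturase Scd1 at -1.01 (SE 0.35); with male_CKD 4 and female_control 2 both left out this list and the atrophy list were not called. Of 21 proliferation genes 19 were negative (median -0.32, camera adjusted p = 0.00299, adjusted p = 0.569 with an estimated correlation), with the replication helicase genes Mcm2 at -0.41 (SE 0.18) and Mcm3 at -0.32 (SE 0.16), and the median was -0.51 without female_CKD 4.

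**Figure D4:**
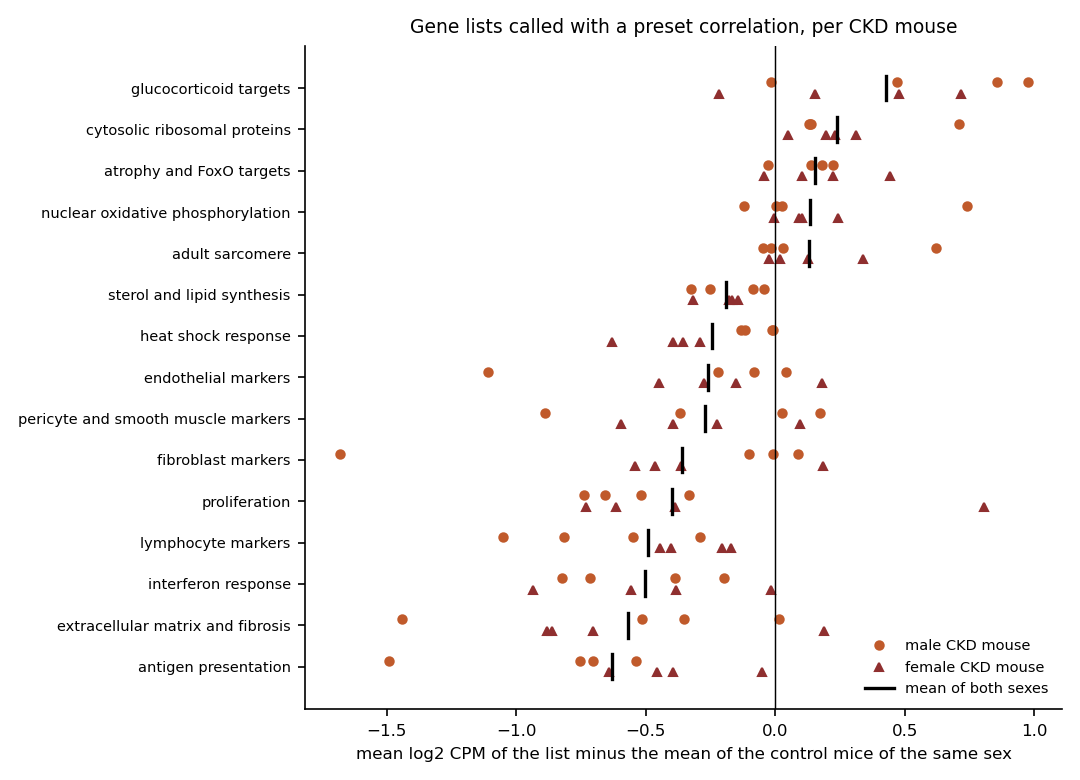
Mean log2 CPM of each of the 15 called lists in every CKD mouse, as the difference from the mean of the control mice of the same sex (circles, males; triangles, females; bars, mean of both sexes). The interferon response, antigen presentation, lymphocyte, sterol and heat shock lists lie below 0 in all 8 CKD mice and the ribosomal list above 0. Male_CKD 4 holds the outermost point of several lists.

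Camera with a correlation of 0.01 called 15 of 43 tested lists, 5 higher and 10 lower, and it compares each list with all other genes. With an estimated correlation 0 lists were called, by fry 0, and by exact permutation of list means within each sex 0, with a lowest adjusted p of 0.0614 for antigen presentation and lymphocyte markers. Those counts are for a shift in a common direction. Fry's test for change in either direction gave adjusted p under 0.05 for some lists. Among the 15 these were interferon response (0.00985), sterol (0.0179), atrophy (0.0269), matrix (0.0302) and antigen presentation (0.0329). Among the others they were NRF2 targets (1.42e-05), hypoxia (0.000674) and inflammatory targets (0.00578). This test was not repeated over other splits of the mice. Over all genes 0 of the 261 members of the 15 lists passed in edgeR, with 95 at an unadjusted p under 0.05, and 23 passed in DESeq2 and 14 in limma-voom. Adjusted over the list alone, 0 members passed in edgeR in the fibroblast, glucocorticoid, oxidative phosphorylation and proliferation lists, where 1, 3, 6 and 1 had an unadjusted p under 0.05; adjusted over all genes, DESeq2 and limma-voom each called 0 in these lists.

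Several further lists were not called. Of 5 aryl hydrocarbon receptor targets 4 were positive (camera adjusted p = 0.0502), Nqo1 being the 1 past the threshold over all genes, and of 13 NRF2 antioxidant targets 10 were positive (camera adjusted p = 0.0824). The hypoxia list (12 members, camera adjusted p = 0.165) held the lower gene P4ha1; its median was 0.00 log2 while its mean was negative. Neutrophil markers were 4 of 5 positive (median 0.53, camera adjusted p = 0.0939), macrophage markers 13 of 17 negative (median -0.10, camera adjusted p = 0.157), and inflammatory cytokine and NF-kB targets 10 of 14 negative (median -0.21, camera adjusted p = 0.165). The 13 mitochondrially encoded genes were all positive by a median of 0.06 (camera adjusted p = 0.157), fatty acid oxidation genes had a median of 0.05 (camera adjusted p = 0.492) and circadian genes 0.06 (camera adjusted p = 0.879).

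In female mice 9 genes differed with CKD, and in male mice 0 did (n = 4 against 4 in each sex). In females Rbm3 rose from 78.3 ± 13.5 to 169 ± 26.1 CPM (log2 fold change 1.11, SE 0.14, adjusted p = 0.00810), as did Rbm3-ps, Gm10156 and Gm48583 (1.25, 1.19 and 1.17). Serpinh1, the collagen chaperone HSP47, fell from 175 ± 34.8 to 78.4 ± 19.6 CPM (log2 fold change -1.16, SE 0.19, adjusted p = 0.0439), and Egln3, a hypoxia-inducible prolyl hydroxylase, from 116 ± 37.4 to 42.7 ± 8.91 CPM (-1.45, SE 0.25, adjusted p = 0.0439). Rflnb fell by 0.92 log2 units (SE 0.16) and Rinl by 1.5 (SE 0.26), each with adjusted p = 0.0439.

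In males the same genes had log2 fold changes of 0.71 (SE 0.14) for Rbm3, -0.42 (SE 0.19) for Serpinh1, -0.50 (SE 0.24) for Egln3, -0.78 (SE 0.16) for Rflnb and -1.03 (SE 0.25) for Rinl. The difference between the sexes, tested as an interaction, passed for 0 genes in edgeR, with 276 genes at an unadjusted p under 0.05 against 820 by chance, and for 0 in DESeq2 and 0 in limma-voom. For Rbm3 that difference was 0.40 (SE 0.19) with an adjusted p of 1.0. All 9 genes called in females had the same sign in males, 7 of them at an unadjusted p under 0.05.

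The 0 genes in males came with 1129 at an unadjusted p under 0.05 and a lowest adjusted p of 0.239 in edgeR; DESeq2 called 12 and limma-voom 0. In females DESeq2 called 32 and limma-voom 55, while edgeR on the 8 female libraries alone called 0, with a lower number of libraries for the spread. Among the libraries with title code number 6 the female count was 3, with Rflnb the 1 shared with the 9, so Rbm3 lost its call there. The female Rinl call was also lost with upper-quartile factors, 1 surrogate variable, GC trends removed, and the title code number or library numbers 3 to 6 as a factor. That of Rflnb was lost with upper-quartile factors and with male_CKD 4 and female_control 2 both left out. Without female_CKD 1 or female_CKD 2 the female count was 0, and without female_CKD 3, male_CKD 1, male_CKD 3 or male_control 4 it was 1. It was 2 without female_control 2 or female_control 3, 4 without female_control 1 or female_control 4, and 13 without male_CKD 4.

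The CKD effects in the 2 sexes, which share no library, correlated across the 16400 genes with a Pearson r of 0.491, and 72.1% of genes had the same sign; genes are not independent replicates. At an unadjusted p under 0.05, 645 genes were higher in males and 682 in females, and 164 were shared against 26.8 for independent lists. Of lower genes, 484 in males and 685 in females shared 144 against 20.2. The r was 0.195 among the libraries with title code number 6.

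As groups, 8 lists had CKD effects that differed between the sexes by camera with the preset correlation, and 0 did with an estimated correlation, where the lowest adjusted p = 0.587, and 0 by fry. Relative to males, the effect in females was more negative for immediate early genes (14 of 14, median difference -0.82 log2, camera adjusted p = 6.78e-06), heat shock genes (10 of 11, -0.35, 0.000558) and glycolysis genes (17 of 19, -0.12, 0.0235). It was more positive for antigen presentation (12 of 13, 0.43, 1.36e-06), erythroid markers (5 of 5, 1.12, 0.000396), fatty acid oxidation (27 of 32, 0.15, 0.000396), proliferation (19 of 21, 0.49, 0.000553) and lymphocyte markers (4 of 7, 0.19, 0.0317). Adjusted over the list alone, 1 lymphocyte marker passed. With the title code number as a factor the immediate early and proliferation lists were not called. Among the libraries with title code number 6 the immediate early, proliferation, heat shock, erythroid and lymphocyte lists were not called. There the antigen presentation list turned direction (median -0.0109), and its median ran from 0.22 to 0.53 with 1 library left out of all 16. Male_CKD 2 held an immediate early mean of 5.15 log2 CPM, against 3.41 to 3.44 in the other 3 male CKD mice, and without it that list was not called. The call was lost for heat shock genes without female_control 4, for fatty acid oxidation without female_CKD 4, for proliferation without female_CKD 4 or male_control 3, and for erythroid markers without male_CKD 1 or female_control 3. It was lost for lymphocyte markers without male_control 2, male_control 3, male_CKD 1, male_CKD 4 or female_CKD 3. For glycolysis genes it was lost without male_control 2, female_control 1, female_control 2 or female_CKD 3, and without male_CKD 4 the test turned to the other direction.

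Apart from Xist and the 4 Y-linked genes, females and males differed in 1 gene among controls and in 2 among CKD mice (n = 4 against 4). Eif2s3x, an X-linked subunit of translation initiation factor eIF2 that escapes X inactivation, was higher in females by 0.93 log2 units in controls (SE 0.12, adjusted p = 0.00277) and by 1.03 with CKD (SE 0.12, adjusted p = 0.000782). Kdm6a, an X-linked histone demethylase that also escapes inactivation, was higher in female CKD mice, at 65.6 ± 6.31 against 26.9 ± 5.78 CPM (1.28, SE 0.19, adjusted p = 0.00754), and in controls its value was 1.01 (SE 0.19, adjusted p = 0.114). Eif2s3x (ENSMUSG00000035150.15) spans chromosome X from 94188707 to 94212862, and Kdm6a (ENSMUSG00000037369.17) from 18162575 to 18279936. In controls DESeq2 called 7 and limma-voom 3 genes; with CKD DESeq2 called 54 and limma-voom with sample quality weights 1549, against 2453 genes at an unadjusted p under 0.05 in edgeR. Without male_CKD 4 the counts were 5 in controls and 5 with CKD, without female_control 2 the count with CKD was 4, and without male_CKD 1 it was 1. On the 8 control libraries alone edgeR called 0.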

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

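The counts over other splits of the mice, the shared sequence of Rbm3, the further chaperone genes and the GC trend in limma-voom were written as tests before their own results were seen, the GC trend in limma-voom after the 1549 genes had drawn attention to it; the other tests of explanations given here, on GC and length trends, male_CKD 4, stromal lists, library numbers and sample quality weights, were chosen only after the results were seen.

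Of 340 groups of 4 libraries examined for a value far from the other 3, 29 had one, where chance gives about 1 in 20, or 17; 13 of the 29 were male_CKD 4. In that library the TMM factor was 0.877, against at least 1.0 in the other 3 male CKD libraries, the correlation of expression with exon length was -0.356, genes outside the range of the other 15 libraries numbered 1411, and its place on component 2 was -80.0. Female_control 2 had 858 genes outside that range. In male_CKD 4, H2-DMb1 was at 1.14 CPM, Rps19 at 292, Atp5o at 1103, Myoz2 at 1489 and Tnnt2 at 7832. Its mean log2 CPM was 8.65 for ribosomal genes, 10.26 for oxidative phosphorylation, 4.40 for fibroblast markers and 11.83 for adult sarcomere genes.

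Other mice stood apart from their group in single genes or lists. In female_CKD 4, Col1a1 was at 36.9 CPM, Sparc at 295 and Pcolce at 33.4, with a matrix list mean of 4.86 log2 CPM, all above the other 3 female CKD mice. In female_CKD 2, Nppb was at 343 CPM, Rinl at 1.01, Hsph1 at 36.8 and Myoz2 at 1469. Hsph1 was at 129 CPM in female_control 4, Myh7 at 2944 in male_CKD 1, Atp5o at 644 in male_control 3 and Arrdc2 at 18.0 in male_control 1. The fibroblast mean of male_control 3 was 6.31 log2 CPM and the ribosomal mean of female_control 3 was 7.87.

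Differences between the sexes in the CKD effect, as medians of female minus male log2 fold changes, stood out for 8 lists with the preset correlation. They were 0.43 for antigen presentation, -0.82 for immediate early genes, 1.12 for erythroid markers, 0.15 for fatty acid oxidation, 0.49 for proliferation, -0.35 for heat shock, -0.12 for glycolysis and 0.19 for lymphocyte markers. Of the 100 splits drawn, 85 gave as many lists as the real 8, and the highest other gave 22, so chance is not excluded.

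Rbm3 and 3 Rbm3-like pseudogenes rose with CKD while all 11 heat shock genes had negative fold changes over all mice. Shared reads are in line with a large common part of the 4 signals: at least 80.8% of the 25-base words of each pseudogene are in Rbm3, and the summed counts gave a log2 fold change of 0.94 (SE 0.11, edgeR adjusted p = 0.00265); yet Rbm3-ps rose by 0.125 log2 units more than Rbm3 (exact permutation p = 0.0396, not adjusted for the 3 pseudogenes; the others 0.174 and 0.438), so a single signal is not settled. Against a GC trend as the whole cause, Rbm3 kept a log2 fold change of 0.85 and its call with the trend removed. The median of the heat shock genes was -0.0112 in males and -0.325 in females, while Rbm3 rose by 0.71 and 1.11 log2 units. Without female_control 4 the heat shock list was not called. Lower activity of the heat shock factor cannot be told apart from none: 13 further chaperone genes differed by -0.10 log2 CPM, 10 of 13 negative, with an exact permutation p of 0.0669, which misses the threshold. As a hypothesis, a lower body temperature with CKD may raise Rbm3; temperature was not part of these data.

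Matrix, fibroblast, endothelial and pericyte lists were lower with CKD by camera with the preset correlation. Male_CKD 4 alone does not account for the matrix list, whose median was -0.49 without it and which was still called. Of the fibroblast, endothelial and pericyte lists 0 of 3 were still called without it. Their mean effects went from -0.346, -0.258 and -0.288 to -0.164, -0.131 and -0.158 log2 CPM. Exact permutation gave p = 0.0559, 0.0727 and 0.104 with this library and 0.118, 0.136 and 0.225 without it, not adjusted over the lists. Male_CKD 4 thus carries those calls, and the remaining effects cannot be told apart from none. With GC and length trends both removed, 3 of the 4 lists were still called and the pericyte list was not. Over the alternative settings the matrix median ran from -0.68 to -0.42. The preset correlation also called a median of 12 lists in other splits of the mice, so these calls cannot exclude a part of such trends. For a lower share of all stromal cells the prediction was that the 4 lists move alike. The matrix effect minus the mean of the 3 marker effects was -0.30 log2 CPM (exact permutation p = 0.0518). A lower share need not move the lists by equal amounts, so the test cannot tell it apart from a change in matrix transcription alone. Lower matrix transcription in CKD may add to the fall of this list, a hypothesis that these bulk counts do not settle.

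Limma-voom with sample quality weights called 1549 genes between the sexes in CKD mice, where edgeR called 2. Without the quality weights limma-voom called 2, which suggests that the weights, 0.166 for male_CKD 4, carry most of the count. With the GC trend subtracted and the weights kept, 678 genes passed, and with the weights estimated anew 40 passed, so the part of GC content cannot be told apart from that of the weights. Among the 8 female mice the libraries numbered 3 to 6 lay at a mean of 53 on component 1 against -8.39 for the other 4 (exact permutation p = 0.0286, the smallest possible). That grouping was chosen because these libraries stood apart, so the p repeats what was seen and is no separate evidence for a cause. Sex itself stays open as a biological cause and was not tested apart from these.

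For the 7 genes higher and the 7 lower with CKD by edgeR, chance is unlikely. The 7 higher features include Rbm3 and its pseudogenes, whose counts cannot be separated with certainty. Of 100 splits, 2 gave as many in a direction, the real one included, yet the highest other gave 915 in 1 direction and 16 in the other. Which part of another split stands for CKD is arbitrary, so 915 is set against both real counts. Among females that split set the libraries numbered 3 to 6 against the other 4; among males it set male_control 3 and 4 and male_CKD 1 and 3 against the rest, which follows no run of library numbers. Several times the real count, it points to a structure of the samples, whose cause was not tested. With library numbers 3 to 6 as a factor, 40 genes were higher and 56 lower with CKD, all 14 among them. DESeq2 called 398 genes in the real split and at most 1077 in the others of 40 splits, 2 of which were as large, the real one included, so for the DESeq2 count chance is not excluded.

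For females, 3 of 35 splits gave as many as the real 9 genes, the highest other gave 2005, and chance is not excluded. The split with 2005 set the libraries numbered 3 to 6 against the other 4; several times the real count, it points to that structure of the samples, and with it as a factor the female count was 9. For males and for the difference between the sexes the real count was 0, so every split is as large by construction (35 of 35, highest other 0, and 100 of 100, highest other 1). These splits therefore neither exclude chance nor speak for it. For sex differences, with 1 gene in controls and 2 in CKD mice, the highest other was at 0 in both. Only the real one, 1 of 35 splits, was as large, so chance is unlikely for these counts. For the 15 lists called with CKD chance is not excluded: 35 of 100 splits gave as many, the highest other gave 23, and the median of the others was 12.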

How the results depend on the processing

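The settings with GC or length trends removed, with library numbers 3 to 6 as a factor, and with male_CKD 4 and female_control 2 left out were chosen after seeing the data, as were the list tests among title code number 6 alone, the exact permutation of list means, the GC trend in limma-voom (though its test was written before its own result) and the correlation of the sexes outside the RLE and stricter filter settings; all others were set before. For counts that moved by over 1.5 times the cause was not tested unless stated.

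The 7 higher genes became 224 with DESeq2, 121 with limma-voom, 24 with no filter, 150 with the title code number as a factor, 3 among title code number 6 alone (fewer libraries), 31 with 1 surrogate variable, 3 against a minimum fold change, 11 with GC trends removed, 15 with GC and length trends removed, 16 with the GC trend removed and male_CKD 4 left out, 40 with library numbers 3 to 6 as a factor and 13 with both outlying libraries left out. The 7 lower genes became 174 with DESeq2, 78 with limma-voom, 29 with no filter, 84 with the title code factor, 26 with 1 surrogate variable, 4 with no sex term, 2 against a minimum fold change, 11 with GC trends removed, 11 with GC and length removed, 15 with GC removed and male_CKD 4 left out, and 56 with library numbers 3 to 6 as a factor. With 1 library left out the counts ran from 4 to 17 higher and from 2 to 26 lower. Scaling moved the split of calls with upper-quartile factors and without mitochondrial genes, each to 5 higher and 7 lower (41.7% higher against 50%), which lost Mr1 and Nt5e.

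In males the count of 0 became 12 with DESeq2, 1 with no filter and 1 with library numbers 3 to 6 as a factor, and ran from 0 to 1 with 1 library left out. In females the 9 genes became 32 with DESeq2, 55 with limma-voom, 3 among title code number 6, 0 on the 8 female libraries alone (fewer libraries) and 15 with the GC trend removed and male_CKD 4 left out, and ran from 0 to 13 with 1 library left out. The count of genes whose effect differed by sex stayed at 0 in edgeR under every setting run, in DESeq2 and in limma-voom, with 276 at an unadjusted p under 0.05. The correlation of the sexes, 0.491, was 0.0621 with no filter, 0.195 among title code number 6 and 0.327 with the GC trend removed and male_CKD 4 left out, and ran from 0.367 to 0.542 with 1 library left out.

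Between the sexes in controls, the 1 gene became 7 with DESeq2, 3 with limma-voom, 3 with no filter, 4 with the title code factor, 3 among title code number 6, 0 on the 8 control libraries alone, 2 with GC removed, 2 with GC and length removed, 4 with GC removed and male_CKD 4 left out and 4 with both outlying libraries left out, and ran from 1 to 5 with 1 library left out. In CKD mice the 2 genes became 54 with DESeq2, 1549 with limma-voom, 4 with no filter, 4 with the title code factor, 5 among title code number 6, 5 with GC removed and male_CKD 4 left out and 10 with both outlying libraries left out, and ran from 1 to 5.

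The 15 lists called with CKD became 0 with an estimated correlation and 0 by fry, and ran from 12 to 19 with 1 library left out. With male_CKD 4 and female_control 2 left out there were 10, and 7 of the 15 were among them. The 8 lists that differed by sex became 0 with an estimated correlation, 0 by fry and 14 with the GC trend removed and male_CKD 4 left out, and ran from 6 to 15. The test turned direction in 4 places. For the list antigen presentation, difference between the sexes, it did so with only title code number 6 (median -0.0109). For the list glycolysis and glucose uptake, difference between the sexes, it did so with GC trend removed, male_CKD 4 left out (0.0717), with male_CKD 4 and female_control 2 left out (0.0246) and without male_CKD replicate 4 (-0.0202, the highest with 1 library left out; the lowest was -0.21 without male_CKD replicate 2). Of 2167 values of named genes under these settings, 1928 kept their direction and side of the threshold, 171 lost a call, 65 gained one, 3 moved and 0 turned direction; of 596 list values 485 kept theirs and 107 lost a call. No paired analysis was possible because the labels give the mice no numbers that pair them.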

Other observations

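The genes and lists named here were chosen after their values were seen. Cirbp, a second cold-inducible RNA-binding protein gene, was at 57.6 ± 13.8 CPM in controls and 96.8 ± 24.2 with CKD (n = 8 each), a log2 fold change of 0.76 (SE 0.16, edgeR adjusted p = 0.0852), with 0.51 in males and 1.02 in females. Over the settings run its adjusted p ranged from 0.00440 with DESeq2 to 0.394 against a minimum fold change. Fmo2, a flavin monooxygenase, was at 61.1 ± 13 and 113 ± 27.4 CPM (0.87, SE 0.17, adjusted p = 0.0805). Aplnr, the receptor of apelin, was at 40.9 ± 20.0 in controls and 15 ± 10.3 CPM with CKD (-1.46, SE 0.35, adjusted p = 0.0946), beside the called fall of its ligand Apln (-1.41).

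Among lists that were not called, all 6 Schwann cell and neuron markers had negative fold changes (median -0.32, camera adjusted p = 0.0565, adjusted p = 0.497 with an estimated correlation), and so had all 5 erythroid markers over all mice (median -0.36, camera adjusted p = 0.0872, adjusted p = 0.642 with an estimated correlation), though the median was -0.88 in males and 0.16 in females. Complement and acute phase genes were positive in 8 of 9 (median 0.19, camera adjusted p = 0.175). Immediate early genes ranged widely between mice, with male_CKD 2 at a list mean of 5.15 log2 CPM.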
